A study of Homo sapiens with 12 samples.

How the data were processed

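The measurements are from 12 Affymetrix whole-transcript arrays, 3 for each of 4 groups: L-428 and L-1236 cells, each transduced with tGFP alone or with tGFP and EBF1. Per the labels, each group holds 3 independent samples of sorted tGFP-positive cells after 8 days of culture. The deposited table holds 1 log2 value per array and row. No source used here states the log base; the values reach 14.3, and a natural or base-10 logarithm of that size would exceed the range of a 16-bit scanner. The summarization and normalization that the authors applied are not given in the sources used here. Array medians lay between 7.19 and 7.31 and interquartile ranges between 2.17 and 2.49. The study's design text states that genes were selected in Bioconductor at a false discovery rate of 5% and a 2-fold change, and those limits were used.

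Of 32321 rows, 19158 carried 1 gene symbol in the platform annotation, 1388 several and 11775 none. The 20546 rows with a symbol were tested. Gene IDs of 19128 of the rows with 1 symbol matched the RefSeq gene table of assembly GRCh38.p14, and no symbol needed updating. Genes were named from rows with 1 symbol, with the exception of EBF1, whose row also lists PDGFRB and carries 3 RefSeq accessions, all of them of EBF1. No genome coordinates are given because the array's build is not stated in the sources used here.

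The deposited log2 values were fitted without further scaling in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 8 residual and 9.98 prior degrees of freedom), with 4 group means over 12 arrays and no block. Contrasts were EBF1 against tGFP in each line, the difference of these effects (L-428 minus L-1236), their mean, and L-428 tGFP against L-1236 tGFP. P-values were adjusted by the Benjamini-Hochberg method within each contrast. A row was called at an adjusted p of 0.05 or less and a change of 2-fold or more, with no fold limit for the difference of effects. Verbs of change are also used of rows that passed the adjusted p alone, with their values.

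A total of 28 gene lists (564 symbols, 506 genes measured) was fixed before the data were examined: B-cell surface, B-cell transcription factor, EBF1 target, antagonist, T and NK, myeloid, Hodgkin marker, NF-kappaB, JAK-STAT, germinal centre, plasma cell, MHC class I and II, cell division, G1/S, p53, interferon, unfolded protein stress, heat shock, immediate early, hypoxia, cholesterol, Notch, adhesion, apoptosis, ribosomal, stromal and erythroid genes. Lists overlap in some members. EBF1 was left out of them, and a gene with several rows was represented by the brightest. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 56 tests for the EBF1 contrasts, with an estimated correlation and with fry beside it. No list was called with an estimated correlation in any contrast. Fry tests whether the genes of a list move one way on average and does not compare them with other genes. A few members with large changes can therefore decide it. It called 1 list in L-428, the B-cell surface genes (fry, adjusted p = 0.00316). In L-1236 it called 2, the B-cell surface genes (fry, adjusted p = 0.00316) and the EBF1 targets (fry, adjusted p = 0.0275).

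Named genes were chosen by a rule fixed before the data were examined. EBF1, CD79A, CD79B, MS4A1, PAX5 and TNFRSF8 were always to be named, and 1 further item of the rule is not reported here. In each EBF1 contrast up to 12 rises and 12 falls were taken among called rows with 1 symbol and no overlap of single arrays. Up to 4 passing members of each list, or 1 or 2 with values where none passed, up to 10 genes called alike in both lines, 6 differences of effect in each direction and 6 baseline differences in each direction were added.

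The fits were tested on simulated arrays with 20546 rows and 50 changed rows per fold size. Both groups of a line were given its control means before the changes were added. The noise had the row variances that eBayes gave, not the rows' own. In L-428, 68% of rows changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 3-fold passed the adjusted p, and in L-1236 the shares were 70% and 100%. Of rows changed exactly 2-fold, 40% in L-428 and 52% in L-1236 also passed the fold limit. Of unchanged rows, 0.0688% in L-428 and 0.0442% in L-1236 passed. The simulated noise was independent between rows and arrays. These shares therefore do not cover deviations that many rows of an array share, which the real arrays showed. Alternatives were quantile normalization, median centring, a filter on dim rows, every row or 1 row per symbol, trend and robust variance, array weights, single-line fits, a replicate block, each replicate left out, other thresholds and an estimated correlation. Added after seeing the data were leaving out both arrays that stand apart, leaving out the EBF1 row from the correlation and the overlap, and a second method of array weighting. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.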

Results

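Gene expression was measured on 12 whole-transcript arrays from L-428 and L-1236, established cell lines derived from Hodgkin lymphoma, a lymphoma whose tumour cells descend from B cells but have lost much of the B-cell expression programme. Each line was transduced either with a control vector carrying the fluorescent protein tGFP or with a vector carrying tGFP and EBF1, a transcription factor required for early B-cell development. Cells were cultured for 8 days and tGFP-positive cells were sorted, giving 4 groups of 3 arrays that the labels describe as independent samples. The number of arrays limits the precision. Within groups, Pearson correlations between arrays over all rows lay between 0.992 and 0.997, and between the lines they lay between 0.944 and 0.953. Array medians ranged from 7.19 to 7.31 on the log2 scale. The interquartile range was 2.28 on replicate 3 of L-428 tGFP against 2.49 and 2.47 on the others of its group, and 2.17 on replicate 1 of L-1236 tGFP/EBF1 against 2.31 and 2.26.

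The transduced gene was measured first. EBF1 signal in L-428 was 8.45 ± 0.16 with tGFP and 12.96 ± 0.027 with tGFP/EBF1 (log2, mean ± SD, n = 3), a 22.8-fold rise (limma, adjusted p = 6.87e-18). In L-1236 it was 7.17 ± 0.057 and 13.15 ± 0.11, a 62.8-fold rise (limma, adjusted p = 4.47e-20). Every tGFP/EBF1 array lay above every tGFP array of its line. The array row is annotated with both EBF1 and PDGFRB, and all 3 of its RefSeq transcripts are those of EBF1. L-428 control cells held 2.42-fold more EBF1 signal than L-1236 control cells (limma, adjusted p = 3.52e-11). The L-1236 control level of 7.17 lay below the medians of those arrays (7.29), and no background signal was used here. The 62.8-fold and 2.42-fold values may therefore be lower limits.

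**Figure D1:**
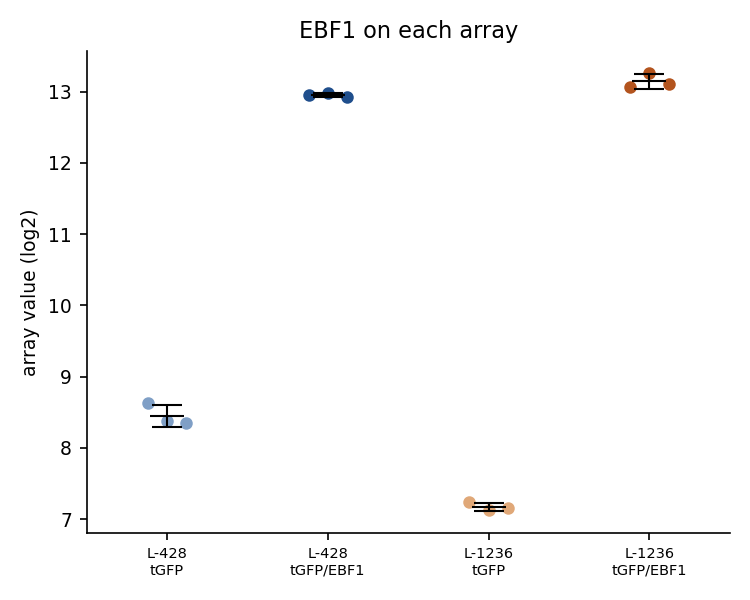
EBF1 signal on each array (log2) in the 4 groups; points are single arrays, the long dash is the group mean and bars are 1 SD (n = 3). Means were 8.45 and 12.96 in L-428 and 7.17 and 13.15 in L-1236, without and with EBF1.

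The first comparison asked which genes differed between L-428 cells with EBF1 and L-428 control cells. The largest rise after EBF1 itself was in FCER2, which encodes the low-affinity IgE receptor CD23 of B cells, from 8.43 ± 0.12 to 10.79 ± 0.018 (mean ± SD, n = 3), or 5.13-fold (limma, adjusted p = 3.5e-14). MRAP2, an accessory protein of melanocortin receptors, rose 3.51-fold, the anion exchanger SLC26A4 3.48-fold and the interferon-gamma-induced chemokine CXCL9 3.13-fold. The other large rises, as log2 changes, were TFPI2 (1.37), a protease inhibitor, SEMA7A (1.31), a membrane-anchored semaphorin, NSMF (1.16), GNG11 (1.15), CAVIN3 (1.10), CHRNA1 (1.09), PRKCH (1.05) and the costimulatory receptor CD40 (1.05). MYBPC2, a muscle myosin-binding protein, fell by 1.88 on the log2 scale, followed by CRLF2, the receptor subunit for thymic stromal lymphopoietin (-1.34), the lipid-raft protein RFTN1 (-1.02) and the germinal-centre signalling protein GCSAM (-1.01). In all, 20 of 20546 tested rows passed an adjusted p of 0.05 with at least a 2-fold change (limma), 16 higher and 4 lower. After quantile normalization 12 higher and 2 lower rows passed, with RFTN1, GCSAM, PRKCH, CD40 and CCL22 just short of 2-fold. Without the fold limit 892 passed, 538 higher and 354 lower, a count that scaling moved to 964 and 650 (quantile normalization) or 345 and 153 (median centring). The standard error of a log2 change had a median of 0.069.

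Among the B-cell genes chosen in advance, CD79A, the immunoglobulin-associated alpha chain of the B-cell receptor, rose by 0.23 in L-428 (limma, adjusted p = 0.0346), a call lost when any of 6 of the single arrays was left out. CD79B (0.056, adjusted p = 0.855), MS4A1 (-0.029, adjusted p = 0.958), PAX5 (0.20, adjusted p = 0.0724) and TNFRSF8 (0.041, adjusted p = 0.927) did not pass in L-428 (limma). Of 19 measured genes known as EBF1 targets in early B cells, 3 rose and 0 fell in L-428 (5 and 0 adjusted over the list alone), and the list lay above the other genes (camera, adjusted p = 0.0271). With an estimated correlation the adjusted p = 0.908. The members that rose were CD40, CD79A and CD53 (0.38). Of 24 B-cell surface and receptor signalling genes, 4 rose and 2 fell in L-428 (5 and 2 adjusted over the list alone). FCER2 and CD40 rose there, and the protein kinase PRKCB (-0.60) and CD24 (-0.34) fell. The list was not called by camera (adjusted p = 0.301) but was by fry, which does not compare it with other genes (adjusted p = 0.00316). Its median was 0.023 and 18 of the 24 genes did not pass, so the fry call does not show a rise over most of the list. Of 18 B-cell transcription factors, 2 rose and 0 fell in L-428 (4 and 0 adjusted over the list alone), the 2 being IRF8 (0.46) and SPIB (0.39) (camera, adjusted p = 0.0977).

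Several cell division genes fell in L-428 with EBF1. Of 21 measured, 0 rose and 5 fell in L-428 (0 and 10 adjusted over the list alone), among them BUB1 (-0.36), KIF20A (-0.34), CCNA2 (-0.30) and CCNB1 (-0.28), and the list median was -0.17 (camera, adjusted p = 8.28e-11). The list mean was 10.59, 10.65 and 10.41 on replicates 1, 2 and 3 of L-428 tGFP. It was 10.39, 10.32 and 10.37 on the EBF1 arrays, so replicate 3 of the controls lay close to them. The list was not called when the correlation was estimated (adjusted p = 0.908 with an estimated correlation). Of 26 DNA replication and G1/S genes, 1 rose and 0 fell in L-428 (1 and 0 adjusted over the list alone), the 1 being CCND1 (0.27), and the list was called higher (camera, adjusted p = 0.0342). With an estimated correlation its adjusted p = 0.908. Of 20 unfolded protein and amino acid stress genes, 4 rose and 0 fell in L-428 (7 and 0 adjusted over the list alone). These were TRIB3 (0.56), DDIT3 (0.46), PPP1R15A (0.37) and ATF3 (0.24) (camera, adjusted p = 0.00685). The list was not called when the correlation was estimated (adjusted p = 0.908 with an estimated correlation). Both of these last lists rested on replicate 3 of L-428 tGFP. The mean over the stress list was 9.84 on that array against 10.10 and 10.12 on the others of its group. Without it the mean change over the stress list was 0.037 in place of 0.13 and no longer called. The mean over the G1/S list was then 0.0011 in place of 0.075, with the direction of the test turned. All 10 splits of the 6 L-428 arrays called at least as many lists as the real 4.

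The remaining lists were not called in L-428. Of 24 immediate early and MAPK feedback genes, 6 rose and 3 fell in L-428 (7 and 4 adjusted over the list alone), with FOS (1.04), ETV5 (0.61) and IER3 (0.48) higher and SPRED2 (-0.38) lower (adjusted p = 0.058). Of 30 NF-kappaB target genes, 6 rose and 1 fell in L-428 (7 and 2 adjusted over the list alone), including rises in TNIP1 (0.49), IER3, CD44 (0.47) and IL6 (0.36). Of 28 Hodgkin/Reed-Sternberg marker genes, 3 rose and 2 fell in L-428 (3 and 2 adjusted over the list alone), with CCL22 (1.03), CD274 (0.91) and PDCD1LG2 (0.41) higher and CLU (-0.35) lower. Of 23 chemokine receptor and lymphocyte adhesion genes, 2 rose and 4 fell in L-428 (2 and 5 adjusted over the list alone), with ITGAL (-0.74), SELPLG (-0.42) and CXCR3 (-0.40) lower (adjusted p = 0.0549). Of 22 JAK-STAT genes, 3 rose and 1 fell in L-428 (5 and 3 adjusted over the list alone), with IL2RA (0.57), PIM1 (0.33) and SOCS2 (0.25) higher and JAK2 (-0.24) lower. Of 15 germinal centre genes, 2 rose and 2 fell in L-428 (2 and 3 adjusted over the list alone), with GCSAM and MYBL1 (-0.28) lower and CD38 (0.49) and EZH2 (0.27) higher. Of 23 BCL2-family and death receptor genes, 3 rose and 0 fell in L-428 (4 and 0 adjusted over the list alone), these being BCL2L11 (0.37), BCL2A1 (0.26) and BMF (0.23). Of 23 T- and NK-cell genes, 2 rose and 1 fell in L-428 (2 and 1 adjusted over the list alone), with IL2RA and PRF1 (0.37) higher and IL2RB (-0.64) lower.

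The other lists were not called in L-428 either. Of 28 type I interferon response genes, 0 rose and 2 fell in L-428 (0 and 2 adjusted over the list alone), these being BST2 (-0.61) and IFIT1 (-0.33). Of 12 MHC class II antigen presentation genes, 2 rose and 0 fell in L-428 (2 and 0 adjusted over the list alone). The risers were IFI30 (0.54) and CTSS (0.37), and no HLA gene of the list passed. Among 10 MHC class I antigen presentation genes, 1 rose and 0 fell in L-428 (4 and 1 adjusted over the list alone), the 1 being PSMB9 (0.32). Of 15 cholesterol synthesis genes, 1 rose and 2 fell in L-428 (1 and 4 adjusted over the list alone), with LSS (0.44) higher and SREBF2 (-0.29) and HMGCS1 (-0.30) lower. Of 25 hypoxia and glycolysis genes, 0 rose and 1 fell in L-428 (0 and 1 adjusted over the list alone), the 1 being ANKRD37 (-0.63), and of 17 Notch pathway genes, 0 rose and 2 fell in L-428 (1 and 2 adjusted over the list alone), these being DLL1 (-0.34) and LFNG (-0.25). Of 15 plasma cell genes, 1 rose and 1 fell in L-428 (3 and 2 adjusted over the list alone), with CD38 higher and ELL2 (-0.27) lower. Of 12 antagonists of the B-cell programme, 1 rose and 0 fell in L-428 (2 and 0 adjusted over the list alone), the 1 being TBX21 (0.32), and of 19 p53 target genes, 1 rose and 0 fell in L-428 (3 and 2 adjusted over the list alone), the 1 being ZMAT3 (0.62). Of 12 heat shock genes, 1 rose and 0 fell in L-428 (2 and 0 adjusted over the list alone), the 1 being CHORDC1 (0.31). Of 27 myeloid and dendritic cell genes, 1 rose and 0 fell in L-428 (3 and 0 adjusted over the list alone), the 1 being LAMP3 (0.33), and of 17 stromal, endothelial and epithelial genes, 1 rose and 0 fell in L-428 (2 and 0 adjusted over the list alone), the 1 being PECAM1 (0.72). None of 22 ribosomal protein genes passed (limma, RPL27 (-0.12) and RPL30 (-0.11) came nearest) and none of 10 erythroid and megakaryocyte genes (EPOR (-0.056) and TAL1 (0.063)). Median, mean and test of a list differed in sign in L-428 for T- and NK-cell, myeloid, Hodgkin marker, NF-kappaB, germinal centre, MHC class II, stromal and erythroid genes.

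**Figure D2:**
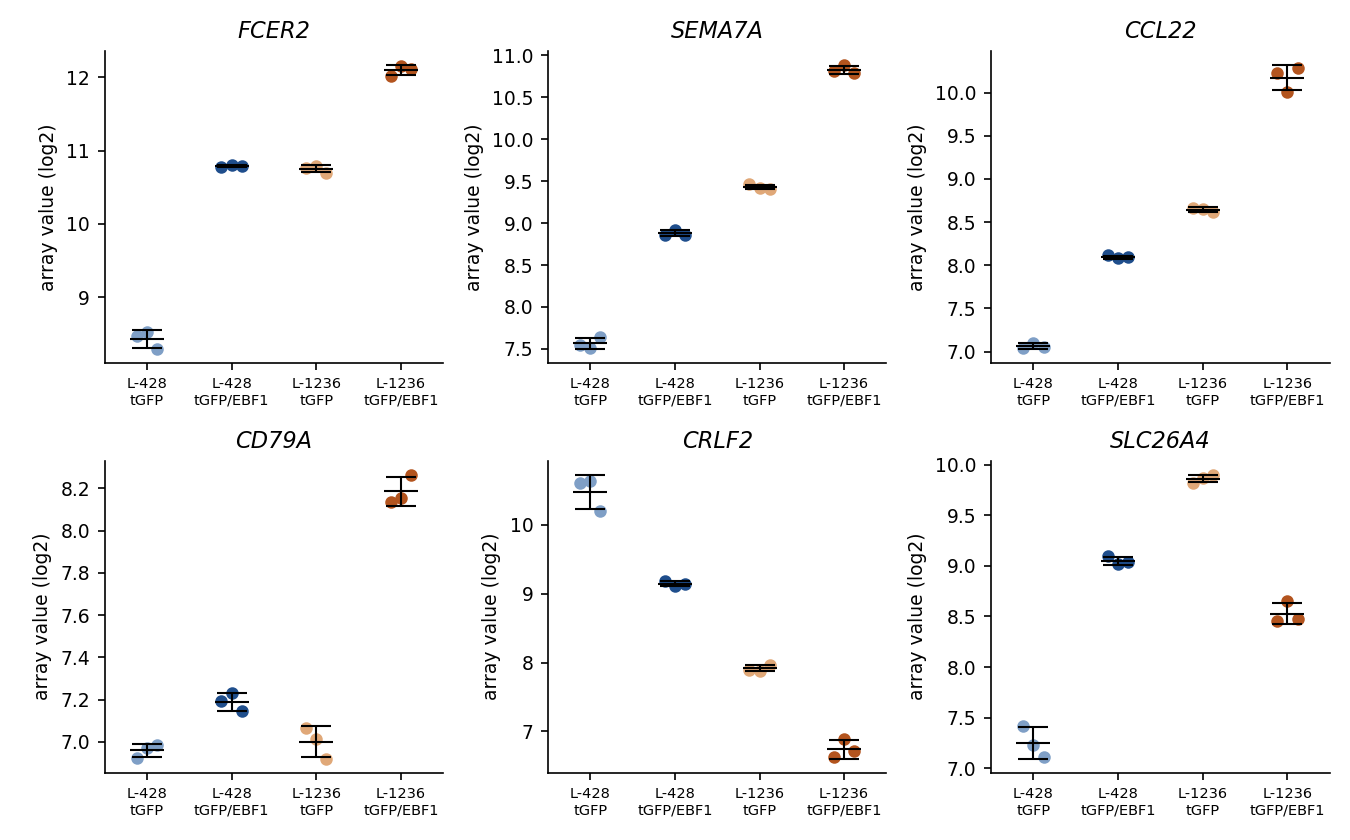
Array values (log2) of 6 genes in the 4 groups; points are single arrays, the long dash is the group mean and bars are 1 SD (n = 3), with a separate vertical scale for each gene. FCER2, SEMA7A and CCL22 rose and CRLF2 fell with EBF1 in both lines, CD79A rose by 0.23 in L-428 and 1.18 in L-1236, and SLC26A4 rose by 1.80 in L-428 and fell by 1.34 in L-1236.

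The same question was asked of L-1236. The largest rise after EBF1 was in SLC22A4, a transporter of organic cations, from 7.30 ± 0.064 to 9.61 ± 0.23 (mean ± SD, n = 3), or 4.97-fold (limma, adjusted p = 3.63e-12). The semaphorin receptor PLXNA1 rose 3.44-fold, the chemokine CCL22 2.89-fold and SEMA7A 2.63-fold. CCR4, the receptor for CCL22, fell by 1.07 on the log2 scale. CD79A rose 2.27-fold (limma, adjusted p = 2.75e-10) and FCER2 2.54-fold. Other large rises were OR5E1P (1.69), FAR2 (1.46), the endocytic receptor LRP1 (1.43), the lymphocyte growth factor IL7 (1.37), CST1 (1.30) and CYP4Z1 (1.26), which has a near-identical pseudogene copy so that its value is uncertain. SLC26A4 fell by 1.34 and the MHC class II chain HLA-DQA1 by 1.19, followed by CYP19A1 (-1.17), CRLF2 (-1.17), HOXB9 (-1.17), MTARC2 (-1.16), DNAI3 (-1.10), CCP110 (-1.09), NMI (-1.02) and NCF4 (-1.01). In all, 30 rows were called (limma), 18 higher and 12 lower, and 1981 passed the adjusted p alone, 759 higher and 1222 lower (1445 and 1618 after quantile normalization, 569 and 792 after median centring). One of the called rows is annotated with several immunoglobulin heavy chain symbols and rose by 1.36.

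Of the other genes chosen in advance, CD79B (0.26, adjusted p = 0.0123) and TNFRSF8, which encodes the Hodgkin cell marker CD30 (0.51, adjusted p = 6.54e-05), rose in L-1236 (limma). MS4A1 (-0.0029, adjusted p = 0.99) and PAX5 (-0.14, adjusted p = 0.187) did not pass. Of the 19 EBF1 target genes, 4 rose and 0 fell in L-1236 (4 and 0 adjusted over the list alone), these being CD79A, CD79B, LEF1 (0.37) and CD40 (0.30) (camera, adjusted p = 0.00623). With an estimated correlation the adjusted p = 0.908. Of the 24 B-cell surface genes, 4 rose and 2 fell in L-1236 (6 and 3 adjusted over the list alone), with CD22 (-0.40) among those lower. The list was not called by camera (adjusted p = 0.0845) but was by fry (adjusted p = 0.00316). Its median was 0.044 and 18 genes did not pass, so here too the fry call does not show a rise over most of the list. Of the 18 B-cell transcription factors, 2 rose and 1 fell in L-1236 (3 and 1 adjusted over the list alone), with LEF1 and IKZF3 (0.26) higher and TCF4 (-0.45) lower (adjusted p = 0.0549).

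Several type I interferon response genes fell in L-1236 with EBF1. Of 28 measured, 1 rose and 9 fell in L-1236 (2 and 9 adjusted over the list alone), including IFIT2 (-0.94), IFIT3 (-0.60), CXCL10 (-0.58) and BST2 (-0.57), and the median was -0.15 (camera, adjusted p = 0.000326). The list was not called when the correlation was estimated (adjusted p = 0.908 with an estimated correlation). Stress genes fell in part as well. Of 20 unfolded protein and amino acid stress genes, 0 rose and 8 fell in L-1236 (0 and 9 adjusted over the list alone), including CEBPB (-0.39), CHAC1 (-0.39), SLC7A11 (-0.37) and DDIT4 (-0.42), and the median was -0.19 (camera, adjusted p = 3.67e-05). With an estimated correlation the adjusted p = 0.908. The mean over the stress list was 9.59, 9.62 and 9.61 on the EBF1 arrays and 9.81, 9.79 and 9.77 on the control arrays. Of the 10 splits of the 6 L-1236 arrays, 3 called at least as many lists as the real 3. Of 12 MHC class II antigen presentation genes, 2 rose and 3 fell in L-1236 (2 and 6 adjusted over the list alone). HLA-DQA1 and HLA-DQB1 (-0.55) were lower and CTSS (0.65) and IFI30 (0.38) higher (camera, adjusted p = 0.0845).

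The other lists were not called in L-1236. Of 28 Hodgkin/Reed-Sternberg marker genes, 7 rose and 5 fell in L-1236 (9 and 7 adjusted over the list alone), with CCL22, NOTCH1 (0.65), CD274 (0.63) and TNFRSF8 higher. Of 30 NF-kappaB target genes, 4 rose and 7 fell in L-1236 (6 and 10 adjusted over the list alone), with BCL3 (-0.63), CCL3 (-0.52) and CCL5 (-0.47) lower and EBI3 (0.43) higher. Of 22 JAK-STAT genes, 5 rose and 0 fell in L-1236 (5 and 0 adjusted over the list alone), with CISH (0.47), BCL6 (0.40), STAT6 (0.39) and SOCS1 (0.33) higher. Of 24 immediate early genes, 2 rose and 4 fell in L-1236 (3 and 6 adjusted over the list alone), with SPRED2 (-0.55), DUSP6 (-0.42), ETV5 (-0.37) and DUSP5 (-0.27) lower. Of 26 DNA replication and G1/S genes, 4 rose and 2 fell in L-1236 (4 and 2 adjusted over the list alone), with MCM10 (0.32) and GINS2 (0.38) higher and CCNE1 (-0.35) and E2F2 (-0.26) lower, and of 21 cell division genes, 1 rose and 0 fell in L-1236 (1 and 0 adjusted over the list alone), the 1 being PLK1 (0.79). Of 23 chemokine receptor and adhesion genes, 3 rose and 3 fell in L-1236 (3 and 3 adjusted over the list alone), with S1PR1 (0.61) higher and SELPLG (-0.55), ALCAM (-0.54) and ITGB1 (-0.45) lower. Of 25 hypoxia and glycolysis genes, 2 rose and 3 fell in L-1236 (2 and 4 adjusted over the list alone), with HK1 (0.75) and SLC2A1 (0.58) higher and BNIP3L (-0.47) and LDHA (-0.32) lower. Of 12 antagonists of the B-cell programme, 1 rose and 3 fell in L-1236 (2 and 3 adjusted over the list alone), with NOTCH1 higher and MSC (-0.52), GATA3 (-0.46) and CEBPB lower.

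The remaining lists were not called in L-1236 either. Of 23 T- and NK-cell genes, 2 rose and 2 fell in L-1236 (3 and 2 adjusted over the list alone), with CD4 (0.48) and CD3D (0.32) higher and IL2RB (-0.68) lower. Of 15 germinal centre genes, 3 rose and 1 fell in L-1236 (3 and 1 adjusted over the list alone), with ELL3 (0.35) and CXCR4 (0.34) higher and GCSAM (-0.63) lower. Of 23 BCL2-family and death receptor genes, 1 rose and 2 fell in L-1236 (1 and 4 adjusted over the list alone), with BMF (0.98) higher and BIRC2 (-0.32) and CFLAR (-0.30) lower. Of 19 p53 target genes, 3 rose and 0 fell in L-1236 (3 and 1 adjusted over the list alone), these being ZMAT3 (0.40), CDKN1A (0.33) and DDB2 (0.23). Of 15 cholesterol synthesis genes, 2 rose and 2 fell in L-1236 (2 and 5 adjusted over the list alone), with SC5D (0.48) and LSS (0.44) higher and MSMO1 (-0.33) and IDI1 (-0.26) lower. Of 15 plasma cell genes, 0 rose and 3 fell in L-1236 (1 and 4 adjusted over the list alone), these being SEC11C (-0.57), XBP1 (-0.31) and FKBP11 (-0.20), and of 12 heat shock genes, 0 rose and 3 fell in L-1236 (0 and 3 adjusted over the list alone), these being CHORDC1 (-0.34), DNAJB1 (-0.35) and HSPD1 (-0.26). Of 17 Notch pathway genes, 1 rose and 2 fell in L-1236 (2 and 2 adjusted over the list alone), with NOTCH1 higher and DLL1 (-0.51) and RBPJ (-0.29) lower. Of 27 myeloid and dendritic cell genes, 1 rose and 2 fell in L-1236 (1 and 2 adjusted over the list alone). CSF1R (0.36) was higher and FCGR2A (-0.67) and CEBPB lower. Among 10 MHC class I antigen presentation genes, 0 rose and 1 fell in L-1236 (1 and 1 adjusted over the list alone), the 1 being PSMB8 (-0.40). No ribosomal protein gene passed (limma, RPL22 (-0.15) and RPS14 (0.15)), nor any erythroid and megakaryocyte gene (EPOR (0.12) and PF4 (0.11)) or stromal, endothelial and epithelial gene (PECAM1 (-0.17) and ACTA2 (0.17)). Median, mean and test differed in sign in L-1236 for antagonist, JAK-STAT, plasma cell and adhesion genes.

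**Figure D3:**
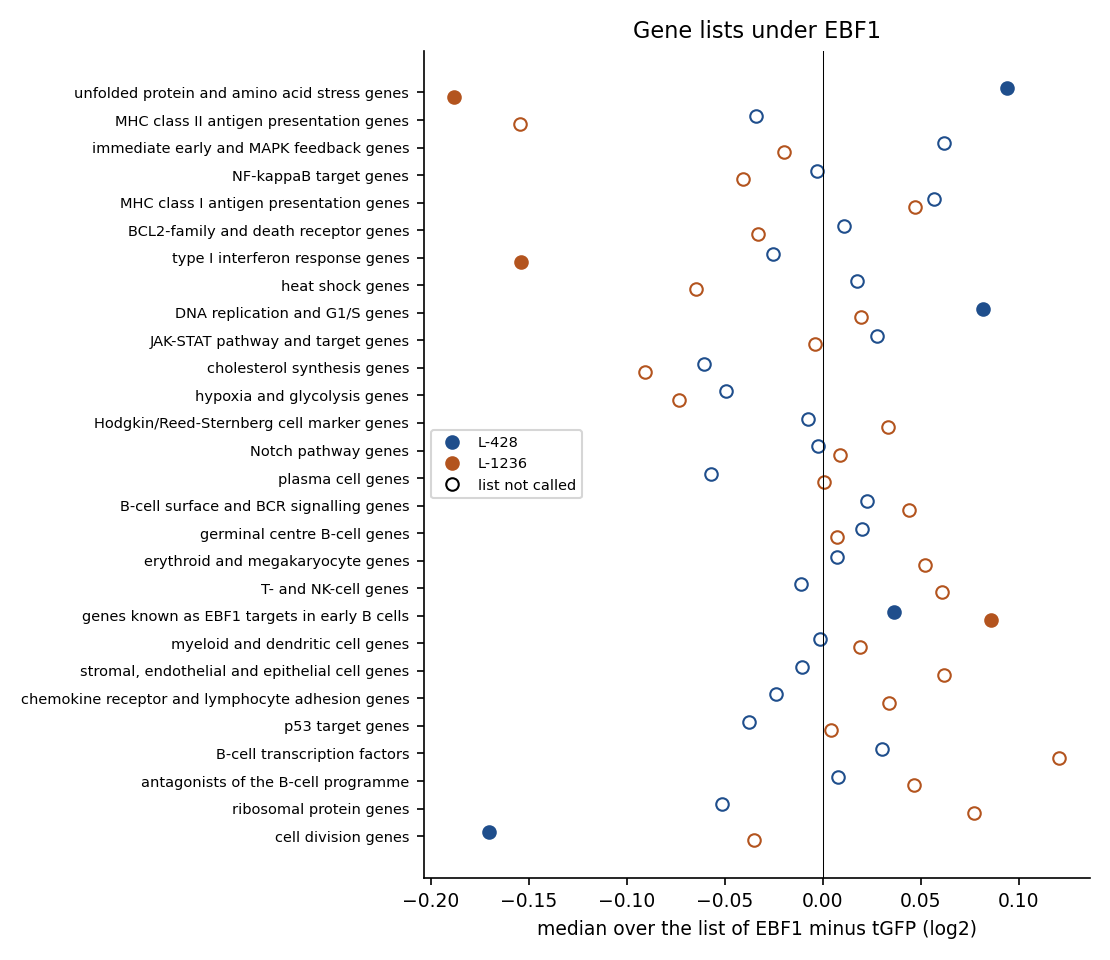
Median over each of 28 gene lists of the EBF1 minus tGFP difference (log2) in L-428 and L-1236; filled points are lists called with the preset correlation and open points are lists not called. The stress list lies at 0.094 in L-428 and -0.19 in L-1236, and none of the lists was called with an estimated correlation.

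Genes that responded alike were sought by comparing the calls of both lines. FCER2, SEMA7A, CCL22 and EBF1 were called higher in both, and CRLF2 lower in both. By the mean of both effects, FCER2 rose by 1.85, SLC22A4 by 1.54, SEMA7A by 1.35, CCL22 by 1.28 and MRAP2 by 1.01, and CRLF2 fell by 1.254, which with EBF1 made 7 called rows (limma). For 2 of these the mean came mainly from 1 line: MRAP2 was at 1.81 in L-428 and 0.20 in L-1236 (adjusted p = 0.0679, not passing), and SLC22A4 at 0.76 and 2.31. Without EBF1, whose rise in both lines was set by the design, the 3 shared rises compare with 0.012 for independent lists of that size (one-sided Fisher's exact p = 2.13e-07) and the 1 shared fall with 0.0023 (one-sided Fisher's exact p = 0.00233). These p-values take rows as independent, and the calls of both lines share 1 estimate of spread per row. The overlap was not counted over other assignments of labels. SLC26A4 was called in opposite directions. At the adjusted p alone, 260 rows moved the same way in both lines, 119 higher and 141 lower against 19.9 and 21.1 for independent lists, and 45 moved in opposite directions, 29 and 16 against 32.0 and 13.1. This overlap at adjusted p alone moved between 130 and 1127 with scaling and weighting. It was 432 without replicate 3 of L-428 tGFP, and 161 and 154 without replicates 2 and 3 of L-428 tGFP/EBF1. Across all tested rows, which are not independent replicates, the effects correlated with r = 0.25 and rho = 0.095, and r = 0.21 without the EBF1 row. Of 100 assignments of labels, the real one included, 17 gave an r as high.

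**Figure D4:**
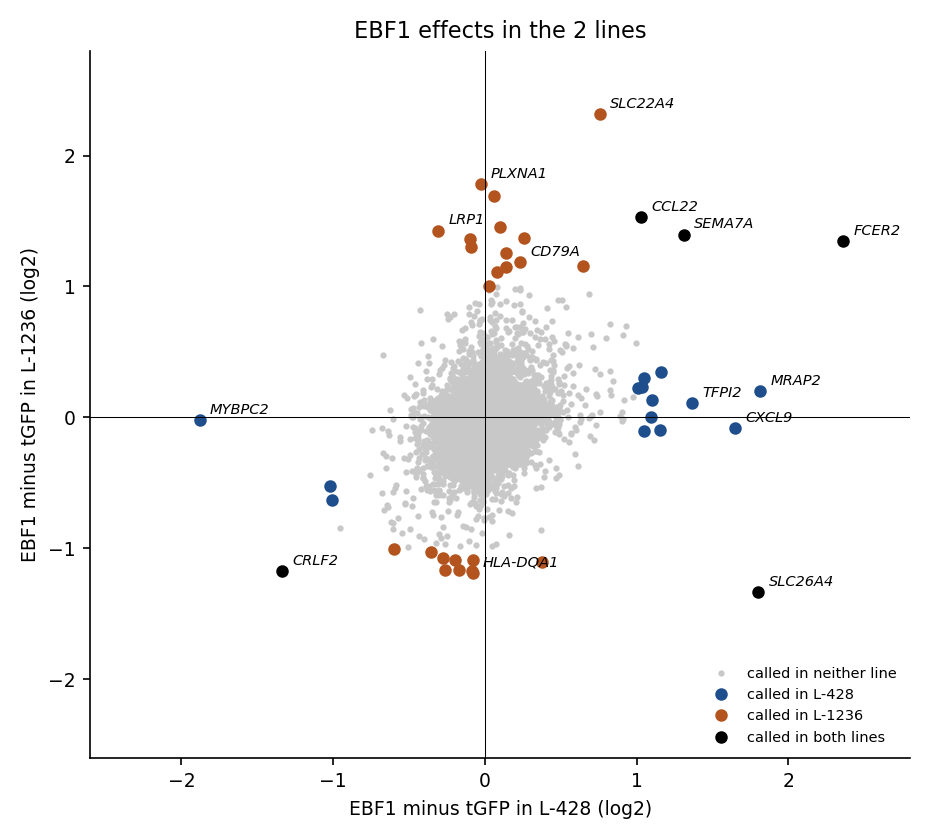
EBF1 minus tGFP difference (log2) in L-1236 against that in L-428 for every tested row except EBF1 itself, with rows called in 1 or both lines in colour or black. FCER2, SEMA7A and CCL22 lie at upper right, CRLF2 at lower left, and SLC26A4 at 1.80 in L-428 and -1.34 in L-1236.

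The last EBF1 comparison tested whether the effect differed between lines. SLC26A4 differed most, by 3.14 ± 0.10 (log2, SE; limma, adjusted p = 1.72e-12). CXCL9, MRAP2, DNAI3, TFPI2 and GNG11 had higher effects in L-428, by 1.73, 1.61, 1.48, 1.26 and 1.2498. MYBPC2, PLXNA1, LRP1, OR5E1P, SLC22A4 and CST1 had lower effects in L-428, by -1.86, -1.81, -1.73, -1.64, -1.56 and -1.39. CD79A rose more in L-1236 (-0.95, adjusted p = 1.79e-06) and FCER2 more in L-428 (1.01, adjusted p = 2.42e-06). PAX5 (0.34, adjusted p = 0.0246) and TNFRSF8 (-0.47, adjusted p = 0.00768) differed between lines (limma), and MS4A1 (-0.026) and CD79B (-0.20) did not pass. In all, 1061 rows differed at the adjusted p, 694 with the higher effect in L-428 and 367 in L-1236, and 32 of them by at least 2-fold. This count (calls interaction) moved between 599 and 4538 with the scaling and weighting of the arrays, and was 672 without replicate 1 of L-428 tGFP/EBF1 and 698 without replicate 2 of L-1236 tGFP.

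Before EBF1, the lines differed widely. The largest differences were higher signal in L-428 control cells of SNORD116-14 (5.97), LRRN3 (5.87), SNORD116-15 (5.66), SNORD116-20 (5.65), FAM9C (5.29) and PIK3CG (5.06), and lower signal of SULF1 (-5.65), SLC16A4 (-5.48), FCER1A (-5.18), AOAH (-4.95), CYSLTR2 (-4.74) and GNAQ (-4.52) (log2). The SNORD116 genes are near-identical copies, so their separate values are uncertain. Of 21 cell division genes, 20 were higher in L-428, with AURKB (1.60) among them (camera, adjusted p = 5.07e-09), as were 19 of 26 G1/S genes, with MCM4 (1.503) (adjusted p = 0.000353). Higher lists in L-428 were also immediate early genes, with DUSP6 (2.47) (adjusted p = 0.000712), MHC class II genes, with HLA-DOA (1.79) (adjusted p = 0.0376), and interferon response genes, with MX2 (2.75) (adjusted p = 0.0376). MHC class I antigen presentation genes were lower in L-428, with TAP1 (-0.92) (camera, adjusted p = 0.024). With an estimated correlation each of these 6 lists had an adjusted p = 0.966. Of 24 B-cell surface genes 8 were higher and 5 lower in L-428, and of 18 B-cell transcription factors 8 were higher and 6 lower, the same counts as when adjusted over the list alone (camera, adjusted p = 0.849 for both). Among them PAX5 (-1.84), CD22 (-2.53) and FCER2 (-2.32) were lower in L-428 and RASGRP3 (3.23) higher. In all, 1479 rows were called (limma), 855 higher and 624 lower in L-428. Scaling moved these to 746 and 684 (quantile normalization) or 970 and 566 (median centring).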

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

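The bounds for the tests in this part were written before their results were seen, except for the test on the stress genes in L-428 alone, the test of the largest difference over all lists and the demand that a value pass its bound by more than its spread, and leaving out both arrays was chosen after the arrays had been seen. That demand was added after the values were known and moved leaving out both arrays and the test of lines meeting in level from excluded to open.

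Among the genes named by rule, 83 had EBF1 effects that differed between the lines at an adjusted p of 0.05 (limma test of the difference). Of these, 53 had the higher effect in L-428 and 30 in L-1236, and EBF1, the transduced gene, is among them. The rule itself took the largest differences passing this test and the largest changes in each line. These counts are therefore no measure of how often effects differ. Over all tested rows, 1061 of 20546 passed. Differences of effects, L-428 minus L-1236 on the log2 scale, were SLC26A4 3.14, CXCL9 1.73, MRAP2 1.61, DNAI3 1.48, TFPI2 1.26, GNG11 1.2498, PRKCH 1.15, HLA-DQA1 1.10, CHRNA1 1.09, CYP19A1 1.09, FCER2 1.01, MTARC2 0.99, ETV5 0.98, CAVIN3 0.96, HOXB9 0.90, PECAM1 0.90, CCP110 0.89 and IFIT2 0.84. Smaller ones were NSMF 0.82, FOS 0.80, CCR4 0.80, TRIB3 0.75, CD40 0.74, CCL3 0.71, IL2RA 0.68, NMI 0.67, CXCL10 0.65, CEBPB 0.64, FCGR2A 0.64, CHORDC1 0.64, IL6 0.62, DNAJB1 0.61, BCL3 0.60, IFIT3 0.59, HLA-DQB1 0.57 and XBP1 0.54. Below these came DDIT4 0.52, IER3 0.48, LDHA 0.47, CCNE1 0.46, LAMP3 0.45, TNIP1 0.45, DDIT3 0.43, CD38 0.42, CD22 0.42, CD44 0.41, E2F2 0.40, EZH2 0.39, PSMB8 0.39, DUSP5 0.36, PAX5 0.34, ATF3 0.34 and TBX21 0.29. Lower effects in L-428 were found for MYBL1 -0.34, CDKN1A -0.36, GCSAM -0.38, TNFRSF8 -0.47, CISH -0.49, ANKRD37 -0.50, RFTN1 -0.50, CCL22 -0.50, NOTCH1 -0.50, CD4 -0.51, CXCR3 -0.53, CLU -0.59, PRKCB -0.59, ITGAL -0.65 and BCL6 -0.67, and the largest of that sign for HK1 -0.68, BMF -0.74, SLC2A1 -0.76, CD79A -0.95, PLK1 -1.04, IL7 -1.12, CYP4Z1 -1.12, FAR2 -1.35, CST1 -1.39, EBF1 -1.46, SLC22A4 -1.56, OR5E1P -1.64, LRP1 -1.73, PLXNA1 -1.81 and MYBPC2 -1.86. The real assignment of labels in both lines gave 1061 such rows in all. Of 100 splits drawn from 200 possible, 3 gave as many, the real one included, and the highest other gave 1876. That one was the real grouping with the labels of 1 line exchanged, so that it measured the mean EBF1 effect. The other gave 1062 and kept the grouping of the L-1236 arrays alone. With 3 of 100, the share of splits as large was under 0.05, but a count this size also arose from the L-1236 effect without the L-428 grouping. Chance assignment of the L-428 labels is therefore not excluded for this count, and the splits do not show by themselves that the lines differ.

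Gene lists that differed between lines by camera with the preset correlation had median differences of 0.32 (unfolded protein and amino acid stress), 0.13 (MHC class II), 0.13 (immediate early and MAPK feedback), 0.070 (type I interferon response), -0.16 (cell division) and -0.14 (ribosomal proteins). None was called with an estimated correlation, where the adjusted p = 0.934 for each of them. Among the 11775 rows with no gene symbol listed, which the comparisons above did not use, 1 was called in L-428, at -1.22, and 4 in L-1236, at 1.84, 1.15, 1.13 and -1.17.

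Replicate 3 of L-428 tGFP and replicate 1 of L-1236 tGFP/EBF1, picked after the values were seen, deviated from their group means with a correlation across rows of r = 0.50. The deviations followed signal level, with rho = -0.66 and -0.48, and a narrower range of values on these arrays is a candidate explanation. Replicate 2 of L-1236 tGFP/EBF1 deviated nearly as much as replicate 1 (SD 0.0932 against 0.103) and the opposite way along signal level (rho = 0.45), so either may be the array out of place in that group. Quantile normalization, which gives every array the same range, took the rho of the picked arrays to -0.14 and -0.10 and their correlation to 0.283, which lies between the bounds set in advance, so how much the range accounts for stays open. The labels name no batch, and no biological explanation was tested.

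The list of unfolded protein and amino acid stress genes had a median of 0.094 in L-428, where 4 of 20 genes rose and 8 had values below 0, and of -0.19 in L-1236, where 8 fell; it was not called in either line when the correlation was estimated (adjusted p = 0.908 with an estimated correlation). This was first taken as 1 pattern of opposite movement and was parted after the values were seen, because the parts behaved differently. The difference between lines had a median of 0.32, with a higher effect in L-428 for 19 of 20 genes. Only 1 of 100 splits was as large, the real one (highest other 0.27, with the L-1236 grouping kept). The list had the largest difference of the 28, and taking the largest over all lists in each split again left 1 of 100. The highest others were 0.298 with the L-1236 grouping kept and 0.297 with the L-428 grouping kept. This excludes only chance assignment of the labels of both lines at once. Chance in 1 line alone is not excluded, because the 6 arrays of a line allow only 10 splits. The splits do not by themselves show that the lines differ. After quantile normalization the median was still 0.270 with a standard error of 0.056. Without both arrays it was 0.229 with a standard error of 0.059 (17 of 20 genes), too close to the bound to exclude them. These standard errors treat the genes of the list as independent, while their estimated correlation was 0.57, so they are too small. An unequal range as the whole cause is therefore not excluded either, although most of the median remained after quantile normalization. For L-428 alone the median without both arrays was -0.028, so the positive median may come from replicate 3 of L-428 tGFP, and a line-specific response remains untested against it.

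SLC26A4 rose in L-428 and fell in L-1236, a difference of 3.14, and after quantile normalization the difference was 3.05, which excludes an unequal range of values as its whole cause. That the lines meet in level under EBF1 over the genes as a whole was tested by correlating the baseline difference, from 1 control replicate, with the difference of effects from the other controls. The correlations were -0.0089, -0.032 and -0.16, the highest being -0.0089, and after quantile normalization -0.082, -0.11 and -0.12, all negative but not all past the bound set for this explanation. The spread of the former is wider than the margin to the bound, so this cannot be told apart from no such relation, and called rows between lines numbered 1479 with tGFP and 1571 with EBF1. A difference in what EBF1 does in each line stays open.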

How the results depend on the processing

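Alternatives added after seeing the data were leaving out both arrays that stand apart, gene-by-gene array weights, and leaving out the EBF1 row from the correlation and the overlap (4 shared calls). The default array weighting, which was planned, warned that it had not converged and gave replicate 3 of L-1236 tGFP/EBF1 a weight of 36.7. The gene-by-gene weighting was chosen after its counts had been seen, and both are given. The causes of the moves below were not tested.

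Counts with the 2-fold limit moved less: over single replicates left out they ranged from 18 to 22 in L-428, 29 to 36 in L-1236, 6 to 7 for the mean effect and 1432 to 1598 at baseline, and 5 shared calls throughout. Quantile normalization gave 14 (12 higher, 2 lower), 36, 6 and 1430 (calls baseline), with 4 shared. The EBF1 rise ranged from 4.46 to 4.60 in L-428 and 5.91 to 6.01 in L-1236, and the correlation of effects from 0.197 to 0.301. Without a fold limit the counts were 892, 1981, 1876 and 9836. These moved with scaling too: rows higher and lower were 538 and 354 in L-428, 964 and 650 after quantile normalization and 345 and 153 after centring, in L-1236 759 and 1222, 1445 and 1618, and 569 and 792, and for the mean effect 893 and 983, 1596 and 1372, and 676 and 578, where the larger side changed. A test against 1.5-fold (treat) gave 12 for the mean effect and 2278 at baseline.

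Counts at the adjusted p alone moved more. Rows differing between lines (calls interaction, 1061) became 1865 with quantile normalization, 599 with median centring, 676 with every row, 4538 with default and 3194 with gene-by-gene weights, 1897 without both arrays, and 672 to 1457 over single replicates left out, the highest without replicate 3 of L-428 tGFP and the lowest without replicate 1 of L-428 tGFP/EBF1. The overlap at adjusted p alone, 260 rows, became 523, 130, 162, 1127, 862 and 526 in that order, and 154 to 432, the highest again without replicate 3 of L-428 tGFP.

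Gene lists called in L-428 (4) became 7 with every row, with default weights and without both arrays, 0 with an estimated correlation, and 3 to 8 over single replicates left out. In L-1236 (3) they became 6 with every row and without both arrays, 0 with an estimated correlation, and 3 to 5. The G1/S list in L-428 turned direction without replicate 3 of L-428 tGFP, alone or with the other array (mean 0.0011), and its highest mean was 0.116 without replicate 2 of that group. Of 168 alternatives for the 7 called lists, 146 kept the call and direction, 20 lost the call and 2 turned. Of 4404 for named genes, 4084 kept both, 303 lost the call, 4 gained one and 13 turned, all in MS4A1 and TNFRSF8, which were not called where they turned. MS4A1 in L-428 was 0.0058 with default weights, 0.0085 gene by gene and 0.010 without both arrays. Without replicate 3 of L-428 tGFP it was 0.010, and 0.025 and -0.080 without replicates 1 and 2 of L-428 tGFP/EBF1. In L-1236 it was 0.014 and 0.011 with the weights, 0.050 without replicate 1 of tGFP and 0.041 and -0.049 without replicates 2 and 1 of tGFP/EBF1. TNFRSF8 in L-428 was -0.027 with either weighting and -0.047 without replicate 3 of tGFP, alone or with the other array, and 0.086 without replicate 2.

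Deviations of arrays sharing a replicate number correlated with 0.23, -0.21 and -0.020 in L-428 and 0.28, -0.074 and 0.19 in L-1236. The highest correlations with another number were 0.021, 0.19 and 0.31 in L-428 and -0.19, 0.060 and 0.26 in L-1236. Replicate 1 matched its own number best in both lines and replicates 2 and 3 did not. So few correlations neither show nor exclude that the numbers pair the arrays. With a replicate block the counts were 20, 30, 7 and 1479, with 1196 differing between lines (calls interaction). No background signal was used here to bound dim rows.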

Other observations

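All tests in this part were set before their results were seen, while the genes of the next paragraph were brought together after their values were seen.

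The ligand and receptor pair CCL22 and CCR4 moved apart in L-1236, where CCL22 rose by 1.53 and CCR4 fell by 1.07 (limma, adjusted p = 8.15e-08). In L-428 CCL22 rose by 1.03 and CCR4 was at -0.27 (adjusted p = 0.0738). The immune checkpoint ligand CD274 rose in both lines, by 0.91 and 0.63, and the Notch ligand DLL1 fell in both, by 0.34 and 0.51. SPRED2, an inhibitor of MAPK signalling, fell in both (-0.38 and -0.55), while ETV5, a transcription factor induced by that pathway, rose in L-428 (0.61) and fell in L-1236 (-0.37), a difference of 0.98 (limma, adjusted p = 3.03e-06). The transporter SLC22A4 rose in both lines, by 0.76 and 2.31.

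How often other assignments of labels give as large a result was counted. Between 6 arrays only 10 splits exist, so a share under 0.05 cannot be reached. In L-428 the real split called 20 rows and the highest other 0, 1 of 10 being as large. In L-1236 it called 30 and the highest other 0, again 1 of 10. At baseline it called 1479 and the highest other 0, 1 of 10. For the mean effect over both lines, 1 of 100 splits called as many as the real 7, with a highest other of 2. This excludes only chance assignment of the labels of both lines at once. It does not show a shared effect, because the 7 rows include EBF1, whose rise was set by the design. They also include MRAP2 and SLC22A4, whose means came mainly from 1 line. Gene lists gave another picture. In L-428 all 10 splits called at least the real 4 lists, the highest other calling 16, and in L-1236 3 of 10 called at least the real 3, the highest other calling 5. In L-428 the other splits called 5 to 16. The preset correlation of 0.01 lay below the estimates for the lists called there, which ran from 0.15 (EBF1 targets) to 0.64 (cell division). List calls at the preset value are therefore reached too easily. That L-428 gave higher counts than L-1236 also points to a structure of the samples whose source was not tested. The correlation of effects, r = 0.25, was reached by 17 of 100 splits, with a highest other of 0.402, so chance assignment is not excluded for it.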
